A study of Mus musculus with 15 samples.

How the data were processed

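The series holds 15 samples of 4C-seq, 1 for each of 3 baits (Pparg, Lpin1, Ifng) in 3T3-L1 cells at days 0, 1, 2 and 6 of adipogenesis and in a B lymphocyte cell line. Per the labels, confluent cells received dexamethasone, 3-isobutyl-1-methylxanthine, insulin and serum on day 0. Chromatin was fixed with 2% formaldehyde for 10 min, cut with HindIII, ligated, cut again with DpnII, ligated into circles and amplified from the bait.

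The authors deposited 27 files, 2 for each 3T3-L1 sample and 1 for each B cell sample, whose values are counts: whole numbers of reads at each of 823355 HindIII sites, with no normalisation. The submitters' processing notes name Bowtie, without a version, and the build mm9. Read filters and any removal of PCR duplicates are not stated. The replicate numbers stand in the deposited names, and the labels do not say whether replicates are separate cultures, so p-values measure the spread between these libraries and not between cultures known to be independent.

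The bait site was taken as the site with the most reads, and all sites within 10 kb of it were left out, because reads there include undigested and self-ligated bait. Of all reads, 3.07% to 93.2% lay on the bait site itself, so the depth left per library, 42094 to 2536087 reads, is not given by its total. On the bait chromosome, reads were summed over windows of 100 kb. On the other chromosomes a site counted as captured with at least 1 read, and captured sites were summed over windows of 500 kb, because reads there are few per site and amplified by PCR: of captured sites on other chromosomes, 14.2% to 74.3% per library had 1 read. A window's captured share is its captured sites over its HindIII sites, and a multiple is that share over the share of all other chromosomes in the same library.

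Windows were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, robust, TMM scaling, 1 fit per bait and part, 5 groups). Same-chromosome windows passed filterByExpr, and other-chromosome windows had a mean of at least 3 captured sites. The contrasts were days 1, 2 and 6 against day 0 and B cells against the mean of the 4 days. Benjamini-Hochberg adjustment was made within a contrast, with a threshold of 0.05. Where windows at an unadjusted p under 0.05 are counted, a share of about 0.05 of the tested windows is expected with no change. The B cell library of a bait is assumed to vary like its 3T3-L1 libraries. CPM are reads scaled by the TMM-scaled total of the tested windows, from edgeR. An interaction fit over all 27 libraries tested whether the day 6 change of Pparg or Lpin1 differed from that of Ifng. The fit was tested on simulated data with changes of 2-fold and 4-fold in 100 windows. Every simulated window was given the common spread of its fit.

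Shares of reads were compared with two-sided exact permutation tests in SciPy 1.17.1. A test of the 3 baits together was chosen after the data were seen to differ in 1 direction, which fixes its p, so only its mean differences are given. Similarity between baits is the Spearman correlation across windows with at least 50 HindIII sites outside chromosomes 6, 10 and 12, with the replicates of a day averaged, 1000 circular shifts within chromosomes as the reference and 1000 resamples of the 17 chromosomes for its interval. The plan named this test two-sided without a convention: sizes were compared first, which ignores that shifted values do not centre on 0, and after the data were seen the p was taken as double the smaller tail, with the first form kept as an alternative. Wilson intervals at 95% are given for shares of reads in a B cell library.

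Windows named in the text follow a rule fixed before the data were examined. For each bait, part and contrast, up to 3 windows per direction are named, by smallest p, among those passing with every library of 1 group beyond every library of the other; adjoining ones are merged. Where none passes, the window with the smallest p in each direction is named as not passing. The 5 windows per bait with the highest captured share are also named. On the bait chromosome these were restricted to windows over 1 Mb from the bait, a restriction added after the data were seen, because nearer windows are nearly all captured. 

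The reference at hand is the RefSeq gene table of GRCm38.p6, another build than mm9. It was used for gene names, for the order of genes around the baits and for protein-coding genes per chromosome, and none of its coordinates are given. The planned tests of gene lists by the windows that hold their genes, and the windows of named adipocyte and lymphocyte genes, were therefore not run.

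The alternatives planned were DESeq2 1.42.0 with its size factors, no filter, the replicate number as a block, windows of 200 kb and 1 Mb, captured sites in place of reads and the reverse, at least 2 reads per captured site, thinning to the shallowest library, zones of 100 kb and 1 Mb around the bait, and leaving out each library in turn. Those added after the data were seen were B cells against the 3T3-L1 files of 1 replicate number, and leaving 2 stretches of chromosome 10 out of the Ifng fit. The share over the 3 baits together was also added then, and the sizes of shifted correlations, used first, became an alternative. Position along a chromosome is the middle of a window over the position of the last HindIII site of that chromosome.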

Results

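The deposited data hold circular chromosome conformation capture with sequencing (4C-seq) of a bait site. The method counts how often other genomic sites were ligated to the bait, as a measure of how often they lay near it in the nucleus. The 3 baits lay at Pparg, which encodes the nuclear receptor that drives fat cell formation, and at Lpin1, which encodes a phosphatidate phosphatase of lipid synthesis. The last lay at Ifng, which encodes the cytokine interferon gamma made by lymphocytes. Each bait was read in 3T3-L1 cells, a mouse fibroblast line that becomes adipocytes under a hormone cocktail, at days 0, 1, 2 and 6 of that process. Each day had 2 replicate libraries. Each bait was also read in a B lymphocyte cell line, with 1 library. The 27 libraries held between 116031 reads (Pparg, day 6, replicate 2) and 3002206 reads (Lpin1, day 1, replicate 1). In every library the site with the most reads was the same for a given bait. These sites lay at 115369246 to 115369251 bp of chromosome 6 for Pparg, at 16597111 to 16597116 bp of chromosome 12 for Lpin1 and at 117870359 to 117870364 bp of chromosome 10 for Ifng, all in mm9. Outside a zone of 10 kb on each side of the bait site, 42094 to 2536087 reads per library were left for the comparisons. The 8 3T3-L1 libraries of a bait are called by day and by the replicate number in the deposited names, and the B cell libraries had no replicates.

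Contacts were densest beside each bait in both cell lines. In the 3T3-L1 libraries, reads within 1 Mb of the bait made up 67.3% ± 2.77 (SD, n = 8) of same-chromosome reads for Pparg, 60.0% ± 3.09 (SD, n = 8) for Lpin1 and 51.5% ± 1.09 (SD, n = 8) for Ifng. The gene order around the baits in the GRCm38.p6 annotation places Timp4, Syn2 and Tamm41 on the low-coordinate side of Pparg. Around Lpin1 it places Trib2, Lratd1 and Nbas on the low side and Ntsr2, Greb1, E2f6 and Rock2 on the high side. Around Ifng it places Iltifb and Il22, which encode lymphocyte cytokines, with Mdm1, Rap1b, Nup107 and Mdm2 on the low side, and Dyrk2, Cand1 and Grip1 on the high side. Farther than 1 Mb from the bait, the windows of 100 kb with the highest share of captured HindIII sites began at 114.3, 116.3, 114.1, 113.8 and 117.2 Mb of chromosome 6 for Pparg, with mean captured shares from 74.6% to 86.2% of their sites. For Lpin1 they began at 15.5, 17.6, 17.7, 13.2 and 21.2 Mb of chromosome 12, with shares from 79.0% to 90.5%. For Ifng, 4 of the 5 lay together about 11 Mb from the bait, beginning at 106.7, 106.8, 107.1 and 107.5 Mb of chromosome 10. The other began at 119000001 bp. Their shares ran from 90.8% to 94.4%. The annotation of the build used for these files was not available, so windows are given by position, without the genes inside them.

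During adipogenesis, day 6 had the lowest mean share of reads on the bait's own chromosome for each of the 3 baits. From day 0 to day 6 the Lpin1 share went from 71.0% ± 7.85 (SD, n = 2) to 58.3% ± 2.55 (SD, n = 2). The Pparg share went from 74.0% ± 0.661 (SD, n = 2) to 70.0% ± 2.99 (SD, n = 2), and the Ifng share from 68.9% ± 1.93 (SD, n = 2) to 66.5% ± 0.703 (SD, n = 2). For each bait both day 6 libraries lay below both day 0 libraries, and with 2 against 2 libraries a two-sided exact permutation test gave p = 0.333 for each bait, the smallest p this design allows. The size of the difference rests on single libraries. For Lpin1 it was -12.7 percentage points, -7.19 without day 0 replicate 1 and -18.3 without day 0 replicate 2. For Pparg it was -3.97, -1.86 without day 6 replicate 2 and -6.09 without day 6 replicate 1. For Ifng it was -2.42, -1.05 without day 0 replicate 1 and -3.79 without day 0 replicate 2. The mean difference over the 3 baits was 3.06 percentage points on day 1, -1.65 on day 2 and -6.38 on day 6. Whether the day 6 change differed between baits was not shown by an exact permutation test. Its p was 0.5 for Pparg and Lpin1, 0.722 for Pparg and Ifng and 0.333 for Lpin1 and Ifng. The smallest p this test could reach was 0.0556. When captured sites were counted in place of reads, the day 6 difference over the 3 baits had the other sign, at 4.05 percentage points. Day 6 libraries also captured the fewest sites of any day. From day 0 to day 6 the mean fell from 29537 to 13625 for Pparg, 27924 to 9041 for Lpin1 and 56594 to 28092 for Ifng. The share of reads on the bait site rose from 7.48% to 56.7% for Pparg and from 60.0% to 90.1% for Ifng. For Lpin1 it fell from 16.6% to 5.75%. A change with adipogenesis cannot be told apart from these differences between libraries.

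**Figure D1:**
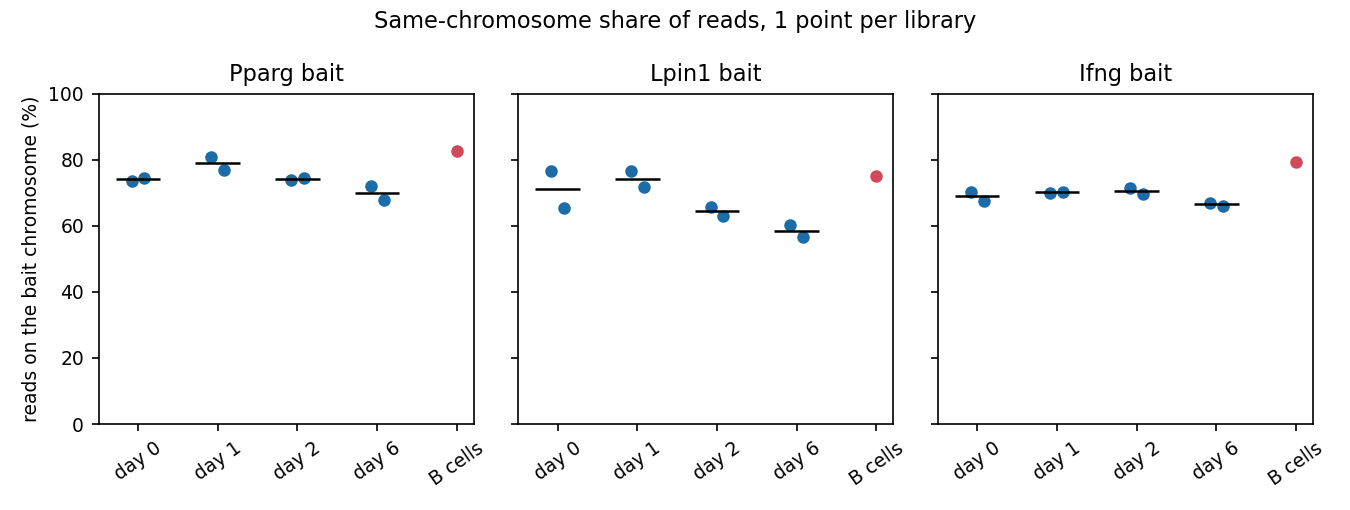
Share of reads on the bait chromosome (%), outside the zone of 10 kb on each side of the bait site, for the Pparg, Lpin1 and Ifng baits. Each point is 1 library, blue for 3T3-L1 days and red for B cells, and black lines are the means of 2 libraries; the day 6 means are 70.0%, 58.3% and 66.5%, and the B cell values are 82.6%, 75.0% and 79.4%.

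In B cells the bait chromosome held more of the reads for Pparg and Ifng than in any of the 8 3T3-L1 libraries of the same bait. The Pparg share was 82.6% in B cells (95% Wilson interval 82.4 to 82.8) against 74.3% ± 3.71 (SD, n = 8). The Ifng share was 79.4% (interval 79.2 to 79.6) against 69.0% ± 1.92 (SD, n = 8). The Lpin1 share was 75.0% (interval 74.9 to 75.1) against 67.0% ± 7.41 (SD, n = 8), above 6 of the 8. Reads within 1 Mb made up 54.2% of same-chromosome reads for Pparg in B cells (interval 53.9 to 54.5), below all 8 3T3-L1 libraries. They made up 59.4% for Ifng (interval 59.2 to 59.7), above all 8. For Lpin1 that share was 58.5% in B cells (interval 58.4 to 58.6), inside the 3T3-L1 range of 54.3% to 63.1%. The Ifng share within 1 Mb also depends on 1 distant stretch of chromosome 10. That stretch took 52.7% of the reads over 1 Mb away in 3T3-L1 cells and 9.38% in B cells. The Wilson intervals treat reads as independent and leave out the spread between libraries. Reads amplified by PCR are not independent molecules, so the intervals are too narrow even for counting error.

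At the Pparg locus, the 1 B cell library had fewer reads than the 3T3-L1 libraries in windows just beyond the bait on both sides. It had more reads in windows farther towards the low-coordinate side. In normalised read counts (CPM, read counts scaled by library), the window at 115.8 to 115.9 Mb of chromosome 6 had 1230 CPM in B cells and 6880 ± 987 (SD, n = 8) in 3T3-L1 libraries, a log2 difference of -2.48 ± 0.47 (SE; edgeR adjusted p = 0.000166). The adjoining windows from 114.7 to 114.9 Mb had log2 differences of -2.09 ± 0.41 and -2.05 ± 0.41 (SE; adjusted p = 0.000313 for each). The windows at 113.8 to 113.9 Mb and from 114.0 to 114.2 Mb were higher in B cells, with log2 differences of 1.96 ± 0.44 (SE), 1.66 ± 0.46 (SE) and 1.69 ± 0.40 (SE). With 1 library left out, the log2 difference of the window from 114.0 Mb ran from 1.47 to 1.95, and its call changed in 5 of 8 cases. In all 12 of 1376 windows of chromosome 6 passed, 3 higher and 9 lower in B cells, and DESeq2 called 36. The count was 7 without the day 0 replicate 1 or the day 1 replicate 2 library, 28 without the day 6 replicate 1 library and 25 without the day 6 replicate 2 library. With captured sites in place of reads the window at 113.8 Mb had a log2 difference of -0.05.

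Along the Pparg time course few windows of chromosome 6 passed, and those that did rested on few reads. The window at 129.7 to 129.8 Mb had 0 reads in both day 0 libraries, 129 and 244 reads in the day 2 libraries, and 9 and 79 reads in the day 6 libraries, and it passed on both days (edgeR adjusted p = 0.0397 and 0.0294). On day 6 the window at 136.1 to 136.2 Mb was higher, at 506 ± 4.35 (SD, n = 2) CPM against 8.56 ± 9.92 (SD, n = 2). The window at 110.4 to 110.5 Mb had 0 reads on day 0 and 1 and 226 reads in the day 6 libraries, and the window at 73.1 to 73.2 Mb had 89 and 626 reads on day 0 and 0 on day 6. On day 1 the count was 0 with edgeR, with 52 windows at an unadjusted p under 0.05 and 6 windows called by DESeq2. The day 1 windows with the smallest p, not passing, began at 107.0 Mb on the higher side (adjusted p = 0.0915) and at 89.4 Mb on the lower side (adjusted p = 0.987), and on day 2 the lower window was at 119.5 Mb (adjusted p = 0.934). The day 2 count of 1 was 0 without any 1 of the day 0 and day 2 libraries. The day 6 count of 4 was 0 without either day 0 library, the day 2 replicate 2 or the day 6 replicate 1 library, and 2 without the day 6 replicate 2 library. DESeq2 called 6 windows on day 2 and 30 on day 6.

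Around Lpin1, 4 windows of chromosome 12 passed on day 6, and their calls depended on single libraries. The windows at 16.5 to 16.7 Mb of chromosome 12, which hold the bait, rose by 0.71 ± 0.15 (SE) and 0.71 ± 0.14 (SE) on the log2 scale (edgeR adjusted p = 0.00285 and 0.000168). With 1 library left out these differences ran from 0.349 to 1.17 and from 0.404 to 1.097, and the call was lost in 4 and 3 of 8 cases. The window at 16.6 Mb went from 110876 ± 36699 (SD, n = 2) to 181649 ± 2449 (SD, n = 2) CPM. The windows at 13.7 to 13.8 Mb and 5.0 to 5.1 Mb were lower on day 6, with log2 differences of -5.19 ± 1.23 and -3.11 ± 0.81 (SE; adjusted p = 0.00978 and 0.0369). In B cells the window at 16.6 to 16.7 Mb was lower than in 3T3-L1 cells by a log2 difference of -0.86 ± 0.15 (SE; adjusted p = 3.38e-05), and so was the window at 15.6 to 15.7 Mb, at -1.42 ± 0.29 (SE; adjusted p = 0.000458). No window passed as higher in B cells, and the one with the smallest p, at 115.2 to 115.3 Mb, had 71 reads in B cells and 0 in the 8 3T3-L1 libraries (adjusted p = 0.409). On days 1 and 2 the counts were 0 with edgeR and with DESeq2, with 20 and 11 of 1154 windows at an unadjusted p under 0.05. The day 1 windows with the smallest p, not passing, began at 16.9 Mb on the higher side and 67.3 Mb on the lower side, and those of day 2 at 29.6 and 116.7 Mb. The day 6 count of 4 was 111 without the day 6 replicate 1 library and 9 without the day 6 replicate 2 library. It was 2 without the day 0 replicate 1 or the day 2 replicate 1 library, and 0 without the day 0 replicate 2 library or either day 1 library. DESeq2 called 126 windows on day 6. The B cell count of 2 was 1 without either day 1 library and 4 and 5 without the day 6 libraries.

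For Ifng, the profile along chromosome 10 differed widely between the cell lines. In 3T3-L1 cells the stretch from 106500001 to 108000000 bp, about 10 Mb from the bait, took 52.7% ± 9.43 (SD, n = 8) of all chromosome 10 reads over 1 Mb from the bait, and in B cells it took 9.38% (95% Wilson interval 9.16 to 9.60). By replicate number the 3T3-L1 mean was 44.5% ± 2.78 (SD, n = 4) for files numbered 1 and 61.0% ± 4.36 (SD, n = 4) for files numbered 2. The share of sites captured in that stretch differed little, at 76.2% ± 4.64 (SD, n = 8) in 3T3-L1 cells and 71.6% in B cells. Beyond 20 Mb from the bait, B cells had 12.9% of chromosome 10 reads, against 5.60% ± 1.73 (SD, n = 2) on day 0 and 6.65% ± 1.45 (SD, n = 2) on day 6. Of 1148 windows of chromosome 10, 263 differed between the lines, 162 higher in B cells with a median log2 difference of 2.11 and 101 lower with a median of -2.44. Of the lower ones, 13 lay in the 106500001 to 108000000 bp stretch. Among the higher windows, the smallest p values lay at 95.3 to 95.4 Mb (log2 difference 3.70 ± 0.50, SE; adjusted p = 2.48e-10), 128.2 to 128.3 Mb (2.61 ± 0.36) and 98.6 to 98.7 Mb (2.86 ± 0.41). Among the lower ones they lay at 72.6 to 72.7 Mb (-4.12 ± 0.69; adjusted p = 4.56e-07), 64.5 to 64.6 Mb (-4.91 ± 0.87) and 123.2 to 123.3 Mb (-2.41 ± 0.47). The window at 95.3 Mb had 628 CPM in B cells and 52.7 ± 24.2 (SD, n = 8) in 3T3-L1 libraries. DESeq2 called 164 windows, 82 in each direction, and counting captured sites in place of reads gave 10. The TMM scaling factor was 1.75 for B cells and 0.605 to 1.36 for the 3T3-L1 libraries.

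**Figure D2:**
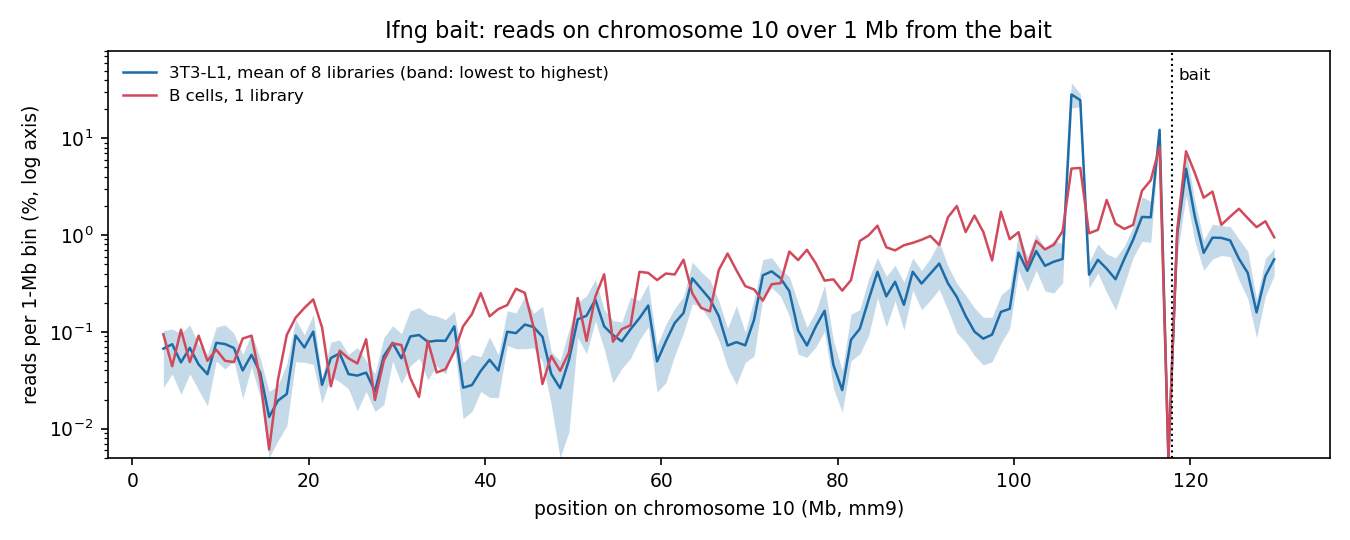
Reads of the Ifng bait along chromosome 10 (mm9, Mb) in bins of 1 Mb, as a percentage on a log axis of the chromosome 10 reads over 1 Mb from the bait. Blue is the mean of 8 3T3-L1 libraries with a band from the lowest to the highest, red is the B cell library, the dotted line marks the bait, and values under 0.005% are drawn at the lower edge; 52.7% of these reads in 3T3-L1 cells and 9.38% in B cells lie between 106500001 and 108000000 bp.

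Along the time course of the Ifng bait, 1 window of chromosome 10 passed, at 110.1 to 110.2 Mb, higher on day 6 than on day 0 by a log2 difference of 1.94 ± 0.46 (SE; edgeR adjusted p = 0.0234). It went from 134 ± 28.04 (SD, n = 2) to 503 ± 77.5 (SD, n = 2) CPM. DESeq2 called 0 windows on day 6. The edgeR count, with 100 windows at an unadjusted p under 0.05, was 0 without either day 0 library, the day 2 replicate 2 library or the day 6 replicate 1 library, and 2 without the day 6 replicate 2 library. On days 1 and 2 the counts were 0 with edgeR and with DESeq2, with 80 and 59 windows at an unadjusted p under 0.05. The windows with the smallest p that did not pass began at 119.7 Mb (higher, day 1, adjusted p = 0.0541), 49.6 Mb (lower, day 1), 83.6 Mb (higher, day 2), 65.9 Mb (lower, day 2) and 28.6 Mb (lower, day 6, adjusted p = 0.0623).

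Of the 5 windows of other chromosomes captured most, the Pparg and Lpin1 baits shared 3, of which 2 adjoin each other. In 3T3-L1 cells both captured the window from 117000001 to 117500000 bp of chromosome 10 most, which lies on the low-coordinate side of the Ifng bait. It was captured at 17.7 ± 6.87 (SD, n = 8) times the mean captured share of other chromosomes for Pparg and 22.1 ± 9.42 (SD, n = 8) times for Lpin1. In B cells these multiples were 8.37 and 8.22. As a share of sites captured, Pparg had 8.11% in B cells and 26.9% ± 11.7 (SD, n = 8) in 3T3-L1 cells, while Lpin1 had 27.03% and 30.3% ± 8.31 (SD, n = 8). The Lpin1 B cell library captured 3.29% of sites on other chromosomes, and its 3T3-L1 libraries 1.73% ± 1.09 (SD, n = 8). Reads gave a larger difference between the lines: from 116500001 to 117500000 bp the read density relative to other chromosomes was 0.115 of the 3T3-L1 mean in B cells for Pparg and 0.0411 for Lpin1, below all 8 3T3-L1 libraries of each bait. For Lpin1 there were 3.04 reads per captured site there in B cells and 99.9 ± 44.4 (SD, n = 8) in 3T3-L1 cells. The window beside it, from 116500001 to 117000000 bp, came next for both baits, at 12.1 ± 3.83 and 14.1 ± 4.22 (SD, n = 8). The window at 3 to 3.5 Mb of chromosome 11 came after it, at 6.58 ± 1.78 and 10.3 ± 3.85 (SD, n = 8). The other leading windows of Pparg began at 32 Mb of chromosome 2 (6.32 times) and 80 Mb of chromosome 10 (6.07 times). Those of Lpin1 began at 77.5 Mb of chromosome 2 (6.69 times) and 46 Mb of chromosome 19 (4.85 times). The Ifng bait had a different set, led by 106000001 to 106500000 bp of chromosome 6, with 13.8 ± 4.82 (SD, n = 8) times the mean in 3T3-L1 cells and 14.6 in B cells. Reads differed more: from 106000001 to 108000000 bp the Ifng read density relative to other chromosomes was 20.8 ± 14.7 (SD, n = 8) in 3T3-L1 cells and 5.33 in B cells. Next for Ifng came windows beginning at 62 Mb of chromosome 16 (11.1 times), 111500001 bp of chromosome 6 (11.0 times), 43.5 Mb of chromosome 16 (10.6 times) and 112000001 bp of chromosome 6 (10.5 times). Each of these 15 windows was above the mean in all 8 3T3-L1 libraries of its bait. They were chosen by their mean over those same libraries, so this is no independent support. Extra copies in 3T3-L1 cells of the stretch from 116500001 to 117500000 bp of chromosome 10 were not tested as a cause of its capture by both baits. On its low-coordinate side, from 115500001 to 116000000 bp, the multiples were 1.03 ± 0.995 for Pparg and 1.08 ± 0.790 for Lpin1 (SD, n = 8).

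**Figure D3:**
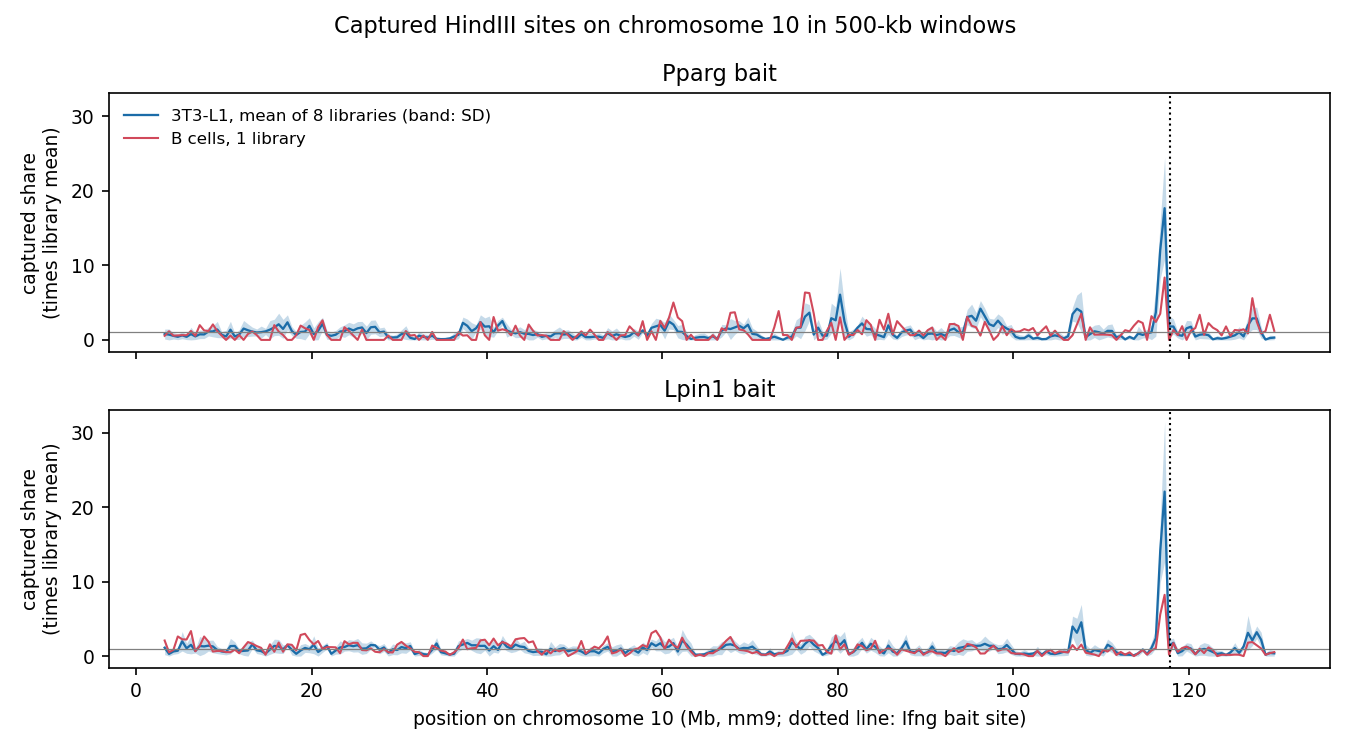
Share of HindIII sites captured by the Pparg and Lpin1 baits along chromosome 10 (mm9, Mb) in windows of 500 kb, as a multiple of the library's mean over other chromosomes. Blue is the mean of 8 3T3-L1 libraries with a band of 1 SD, red is the B cell library and the dotted line marks the Ifng bait site; the peak from 117000001 to 117500000 bp reaches 17.7 for Pparg and 22.1 for Lpin1 in 3T3-L1 cells.

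The bait loci themselves, taken as 500 kb on each side of the bait site, had mean captured shares above that of other chromosomes from the Pparg and Lpin1 baits in 3T3-L1 cells. From Lpin1, the Ifng locus was captured at 2.40 ± 0.676 and the Pparg locus at 2.02 ± 0.970 (SD, n = 8) times the mean. From Pparg, the Ifng locus was captured at 2.36 ± 0.957 and the Lpin1 locus at 1.61 ± 0.350 (SD, n = 8) times the mean. The Ifng locus shares sites with the window from 117000001 to 117500000 bp that both baits captured most. From 118000001 to 119000000 bp, away from that window, the shares were 1.08 ± 0.335 times the mean for Lpin1 and 1.23 ± 0.412 times for Pparg (SD, n = 8). From Ifng, the Pparg locus stood at 0.955 ± 0.234 and the Lpin1 locus at 0.680 ± 0.256 (SD, n = 8). In B cells the same 6 multiples lay between 0.464 and 1.26, each from 3 to 13 captured sites.

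With windows of 500 kb, none on another chromosome passed between day 0 and a later day for any of the 3 baits, by edgeR on captured sites or by DESeq2. With windows of 1 Mb, Pparg had 1 on day 2 and 2 on day 6, and without the day 0 replicate 1 library Lpin1 had 1 on day 2. At an unadjusted p under 0.05 there were 77 to 130 of 1969 windows for Pparg, 113 to 158 of 2250 for Lpin1 and 130 to 165 of 4134 for Ifng. Against the share of 0.05 expected with no change, Ifng lay below, Pparg on both sides and Lpin1 above. The day 6 windows with the smallest p, not passing, were, for Pparg, 189000001 to 189500000 bp of chromosome 1 (higher) and 61 to 61.5 Mb of chromosome 18 (lower, adjusted p = 0.160 for both). For Lpin1 they were 42 to 42.5 Mb of chromosome 15 (higher) and 107000001 to 107500000 bp of chromosome 10 (lower, adjusted p = 0.551 for both). For Ifng they were 56 to 56.5 Mb of chromosome 11 (higher) and 74.5 to 75 Mb of chromosome 4 (lower, adjusted p = 0.986 for both). On day 1 the higher and the lower window began at 108000001 bp of chromosome 7 and 149000001 bp of chromosome 5 for Pparg, and at 112500001 bp of chromosome 11 and 12.5 Mb of chromosome 10 for Lpin1. For Ifng they began at 117500001 bp of chromosome 6 and 54 Mb of chromosome 8. On day 2 they began at 50 Mb of chromosome 4 and 79.5 Mb of chromosome 15 for Pparg, and at 36 Mb of chromosome 1 and 107000001 bp of chromosome 10 for Lpin1. For Ifng they began at 126.5 Mb of chromosome 8 and 44.5 Mb of chromosome 5. Whether the day 6 change of Pparg or Lpin1 differed from that of Ifng was tested directly on 3286 windows. There were 0 calls by edgeR for each, with 199 and 178 windows at an unadjusted p under 0.05, and 0 calls by DESeq2, but 1 call for each with windows of 1 Mb. With 1 common spread in the simulated data, the edgeR fit recovered 27% of 4-fold changes for Pparg, 12% for Lpin1 and 48% for Ifng. It recovered 0% to 4% of changes of 2-fold, so that a change of 2-fold would mostly be missed at that spread.

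Between B cells and 3T3-L1 cells, windows on other chromosomes passed for Lpin1 and Ifng, and each of them was captured more in B cells. For Ifng these were 18 windows on 11 chromosomes, all beginning at 84.5 Mb or beyond. The naming rule took only windows with B cells beyond all 8 3T3-L1 libraries, so that separation is by selection. It gave 3 of these windows, by smallest p. The first of these was 138.5 to 139 Mb of chromosome 3 (log2 difference 2.69 ± 0.47, SE; edgeR adjusted p = 0.00349). The others were 115000001 to 115500000 bp of chromosome 9 (2.45 ± 0.43) and 136000001 to 136500000 bp of chromosome 3 (2.32 ± 0.45). For Lpin1 they were 5 windows, at 6 to 6.5 Mb of chromosome 2 (1.82 ± 0.43; adjusted p = 0.0277), 20 to 20.5 Mb of chromosome 13 (2.38 ± 0.57), 23.5 to 24.5 Mb of chromosome 11 (2.53 ± 0.63 and 2.44 ± 0.61) and 60 to 60.5 Mb of chromosome 19 (3.16 ± 0.79). The last and the window from 23.5 Mb are named outside the rule for named windows, after their values were seen. For Pparg the count was 0 with edgeR and with DESeq2, with 135 windows at an unadjusted p under 0.05. The windows of Pparg with the smallest p, not passing, were 87.5 to 88 Mb of chromosome 12 (higher, adjusted p = 0.0586) and 5 to 5.5 Mb of chromosome 19 (lower, adjusted p = 0.519). The lower window of Lpin1 closest to passing was 77.5 to 78 Mb of chromosome 2 (log2 difference -1.73 ± 0.48; adjusted p = 0.0692), and that of Ifng was 29.5 to 30 Mb of chromosome 18, with 0 captured sites in B cells (adjusted p = 0.105). The lower window of Pparg also had 0 captured sites in B cells. Since even such windows did not pass, the shared direction cannot be read as a lack of losses in B cells. The filter, a mean of at least 3 captured sites, counted the B cell library, so a gain there could bring a window into the test. The Lpin1 window at 24 to 24.5 Mb of chromosome 11 had 16 captured sites in B cells and 0 to 3 per 3T3-L1 library. DESeq2 called 0 windows for Lpin1 and Ifng, and edgeR had 532 windows for Ifng and 255 for Lpin1 at an unadjusted p under 0.05. The Ifng count was 28 without the day 0 replicate 1 library, 8 without the day 1 replicate 1 library and 3 without the day 1 replicate 2 library. The Lpin1 count was 9 without the day 0 replicate 1 library, 1 without the day 0 replicate 2 library, and 0 without the day 1 replicate 1, the day 2 replicate 1 or either day 6 library.

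Whether baits of fat cell genes meet the same regions of other chromosomes was asked across 4352 windows outside the 3 bait chromosomes. In 3T3-L1 cells the captured shares of Pparg and Lpin1 followed each other closely, with a Spearman rho of 0.730 (95% interval over resampled chromosomes 0.703 to 0.754) on day 0, 0.574 on day 1, 0.657 on day 2 and 0.438 (interval 0.390 to 0.477) on day 6. For Pparg and Ifng rho was -0.231 on day 0, -0.124 on day 1, -0.076 on day 2 and 0.0023 on day 6. For Lpin1 and Ifng it was -0.173 on day 0 and -0.107 on day 6. The Pparg and Lpin1 rho exceeded the Pparg and Ifng rho by 0.961 (interval 0.790 to 1.11) on day 0 and 0.435 (interval 0.327 to 0.531) on day 6. In B cells the 3 pairs stood closer, at 0.338 for Pparg and Lpin1, 0.330 for Pparg and Ifng and 0.178 for Lpin1 and Ifng, and the first exceeded the second by 0.0077 (interval -0.039 to 0.065). With all libraries thinned to 1 depth that difference was -0.0702 (interval -0.117 to -0.0224). With p as double the smaller tail, a form chosen after the data were seen, each rho differed from those of windows shifted along their chromosomes (permutation p = 0.002, the smallest possible with 1000 shifts), whose means lay between 0.053 and 0.105. With sizes compared, the form used first, the permutation p was 0.169 and 0.170 for Lpin1 and Ifng on days 1 and 2, and 0.718 and 1 for Pparg and Ifng on days 2 and 6. With at least 2 reads per captured site, the doubled p of the last was 0.0719. Windows along a chromosome are not independent replicates, and the day 6 libraries of Lpin1 captured 5812 and 12270 sites against 25492 and 30356 on day 0. Thinned to the reads of the shallowest library, the fall of the Pparg and Lpin1 rho from day 0 to day 6 was -0.220 (interval -0.254 to -0.182) against -0.293 without thinning. Thinning matches reads and not captured sites. Lpin1 day 6 replicate 1 had 12270 captured sites in 1657988 reads, and day 0 replicate 1 had 30356 in 1453951. The fall that remains is therefore not set apart from the smaller number of captured sites on day 6. Captured share also varied with the number of HindIII sites in a window. In 3T3-L1 cells its mean rho with that number was -0.275 for Pparg, -0.232 for Lpin1 and 0.0398 for Ifng (n = 8 each). In B cells it was -0.254, -0.246 and -0.194. How much of the similarity between baits goes with the number of sites was not tested.

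**Figure D4:**
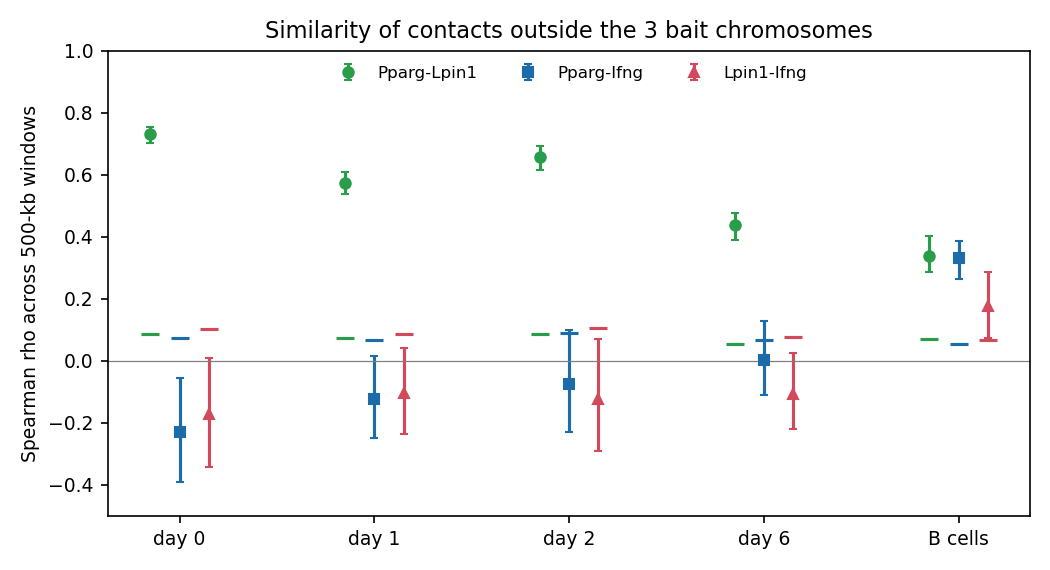
Spearman rho across 4352 windows of 500 kb between the captured shares of each pair of baits, by day of adipogenesis and in B cells. Points are the rho with 95% intervals from resampled chromosomes, and short horizontal marks are the means after shifting windows along their chromosomes; the Pparg and Lpin1 pair goes from 0.730 on day 0 to 0.438 on day 6, and stands at 0.338 in B cells.

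Libraries of the same day always have different replicate numbers. On average they were more alike than libraries of different days with different numbers, for each bait. They were no more alike than libraries of different days with the same number. The ranges overlapped, and these differences were not tested. Within the 3T3-L1 libraries of Pparg, the mean Spearman rho of captured shares was 0.553 for the same day. For different days it was 0.587 with the same replicate number and 0.529 with different numbers. These 3 values were 0.502, 0.513 and 0.486 for Lpin1, and 0.636, 0.639 and 0.627 for Ifng. For Pparg the replicate number also went with depth. Its 3T3-L1 files numbered 1 held 1718012 to 2551475 reads, and those numbered 2 held 116031 to 429788. The B cell library stood apart from the 3T3-L1 libraries for Ifng, with a mean rho of 0.381 and a highest value of 0.432, below the lowest value of 0.517 between 3T3-L1 libraries. For the other baits the values overlapped: the mean rho with the B cell library was 0.538 for Lpin1, and 0.395 for Pparg, with a highest value of 0.442 against a lowest of 0.358 between 3T3-L1 libraries.

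How often a region of another chromosome was captured varied with its position along that chromosome. For the Ifng bait, which lies near the high-coordinate end of chromosome 10, the last of 5 equal parts of the other chromosomes was captured at 1.31 ± 0.0729 (SD, n = 8) times the mean in 3T3-L1 cells and 1.64 times in B cells. The first part was captured at 0.841 ± 0.0688 (SD, n = 8) and 0.618 times. For Pparg, the last part stood at 1.39 ± 0.0719 (SD, n = 8) in 3T3-L1 cells and 1.54 in B cells, and the first part at 0.747 ± 0.0601 (SD, n = 8) and 0.573. For Lpin1, which lies near the low-coordinate end of chromosome 12, the last part stood at 1.12 ± 0.0271 (SD, n = 8) in 3T3-L1 cells and 0.877 in B cells, and the first part at 1.02 ± 0.0265 (SD, n = 8) and 1.22.

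**Figure D5:**
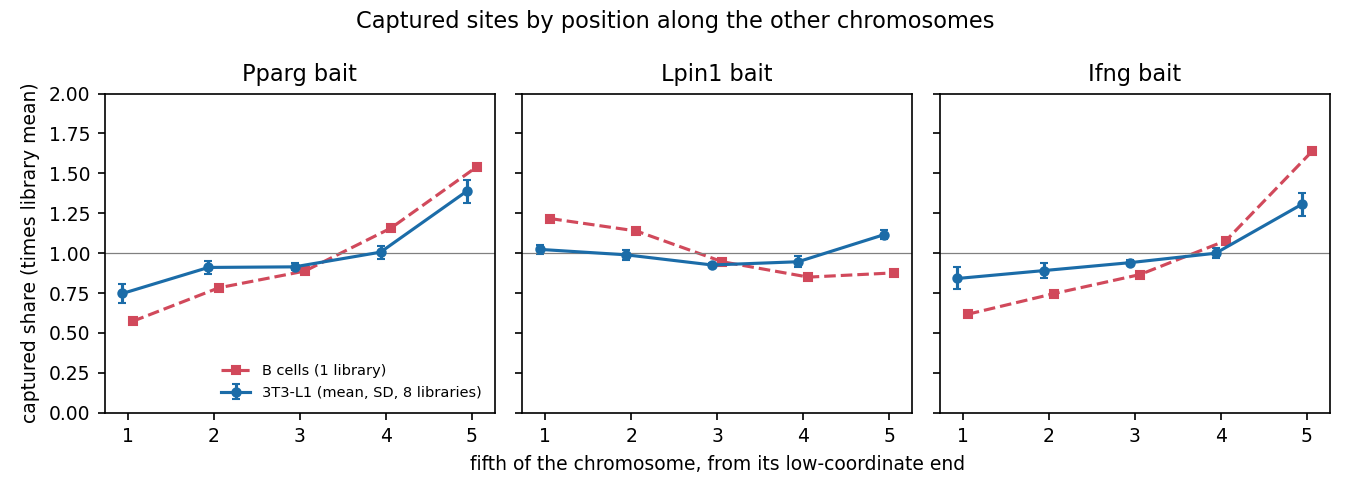
Captured share of HindIII sites in 5 equal parts of the chromosome, from the low-coordinate to the high-coordinate end, over chromosomes without a bait, as a multiple of the mean. Blue is the mean of 8 3T3-L1 libraries with 1 SD and red the B cell library; from the first to the last part in B cells the multiples go from 0.618 to 1.64 for Ifng and from 1.22 to 0.877 for Lpin1.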

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

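The tests of unequal read draw, extra copies, B cell contact strength and carry-over with reads thinned were chosen only after the results were seen; the first carry-over test was set beforehand.

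Around Pparg and around Ifng the share of same-chromosome reads within 1 Mb of the bait moved in opposite directions between the cell lines. In B cells it differed from the 3T3-L1 mean by -13.0 percentage points for Pparg, below all 8 3T3-L1 libraries, and by 7.91 for Ifng, above all 8. This share also depends on the reads farther from the bait. For Ifng, the stretch from 106500001 to 108000000 bp of chromosome 10 took 52.7% of the reads over 1 Mb away in 3T3-L1 cells. In B cells it took 9.38%. The share without that stretch was not computed, so opposite directions are not shown for contacts near the baits. The difference between the baits was not tested, and B cells have 1 library per bait.

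Chromosome Y, with 855 HindIII sites, was counted among the other chromosomes and left out of the comparisons of similarity and position. It held 30 reads in the Pparg, 360 in the Lpin1 and 45 in the Ifng library of the B cells. The highest 3T3-L1 library of each bait held 5, 24 and 7.

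The Ifng bait took 52.7% of its chromosome 10 reads over 1 Mb from the bait from 106500001 to 108000000 bp in 3T3-L1 cells, and 9.38% in B cells. Sequence that draws reads in any cell is argued against as the whole cause. The B cell read density there, relative to other chromosomes, was at most 0.258 of the 3T3-L1 mean over the 3 baits. As a part of the cause it stays open. The Ifng bait captured 71.6% of the sites there in B cells and 76.2% ± 4.64 (SD, n = 8) in 3T3-L1 cells. Its B cell read density there was 6.27 times that of the flanks. Extra copies of the region in 3T3-L1 cells stay open. Pparg and Lpin1, on other chromosomes, captured the region at 4.92 times its flanks or more with the 3T3-L1 libraries of each bait pooled. In B cells the values were 4.10 and 3.23 times, so that the excess was not shown to be particular to 3T3-L1 cells. These B cell values rest on 10 and 21 captured sites, and carry-over of 3T3-L1 reads into those libraries was not tested. Whether extra copies alone account for the Ifng reads from this region cannot be told apart from a contact of the Ifng bait. The read density over the flanks was 11.9 times as high from Ifng as from the other baits when pooled, and over 2 times in 120 of 128 library pairs, but 0.600 in the lowest pair. The other 8 pairs all held the Pparg library of day 0 replicate 2, without which, a choice made after the ratios were seen, the lowest was 2.02, so this rests on 1 library.

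In the Ifng B cell library, the chromosome 6 regions at 106000001 to 108000000 bp and 111500001 to 112500000 bp, which hold 3 of the 5 windows captured most by this bait in 3T3-L1 cells, had captured shares of 11.3 to 14.6 times the mean in those windows. Contacts of the B cells as strong as those of 3T3-L1 cells stay open: the ratio of B cell to 3T3-L1 reads there was at most 0.209 of that over all other chromosomes, but by replicate number it was 0.139 and 0.127 against files numbered 1 and 0.664 and 0.674 against files numbered 2, on both sides of the 0.5 set as the bound. For carry-over of 3T3-L1 reads, the test set beforehand compared, site by site, B cell with 3T3-L1 reads: rho was 0.569 in these regions and 0.897 beside the bait, a difference of -0.329 (interval -0.373 to -0.285), which met the bound set against carry-over. That bound was wrong, because the B cell library had 0.335 reads per site in these regions and 69.4 beside the bait, and a deeper set gives a higher rho. With the B cell reads beside the bait thinned to 0.335 per site the difference was 0.0538 (interval 0.00111 to 0.107), and with the 3T3-L1 reads thinned as well, from 468 to 35.4 per site, it was 0.0497 (interval -0.00514 to 0.104), both short of the 0.1 that carry-over was set to need, so carry-over and contacts in B cells cannot be told apart.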

How the results depend on the processing

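Comparing B cells with files of 1 replicate number, leaving 2 stretches of chromosome 10 out, and taking the share over the 3 baits together were chosen only after the data were seen. The sizes of shifted correlations, the form used first, were also made an alternative only then. The others were planned. In all, 110 results were recomputed under 1403 alternatives, and 1143 kept their direction and side of the threshold or stayed within their spread or within 1.5 times the count. The cause of the changes below was not tested. The replicate numbers were not taken to pair the files, since not every correlation of window deviations between days by number was over 0.1: they ran from -0.0452 to 0.0544 on the same chromosome and from 0.0035 to 0.327 on other chromosomes. Files did differ by number for Ifng from 106000001 to 108000000 bp of chromosome 6, which took 2.87% ± 0.789 (SD, n = 4) of other-chromosome reads in files numbered 1 and 0.720% ± 0.156 (SD, n = 4) in files numbered 2.

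With DESeq2 the same-chromosome counts for Pparg were 6 on day 1, 6 on day 2, 30 on day 6 and 36 in B cells; for Lpin1 126 on day 6; for Ifng 0 on day 6 and 164 in B cells; the other-chromosome counts in B cells were 0 for Lpin1 and 0 for Ifng. With no filter they were 0 for Pparg on day 2, 1 for Ifng on day 1 and, on other chromosomes, 1 for Pparg in B cells. With the replicate block, same-chromosome counts were 0 for Pparg on days 2 and 6, and 1 and 7 for Ifng on days 1 and 6; other-chromosome counts in B cells were 2 for Pparg, 0 for Lpin1 and 10 for Ifng. With 200-kb windows they were 0 and 0 for Pparg on days 2 and 6 and 22 in B cells, 1 for Lpin1 on day 6 and 0 in B cells, and 3 and 7 for Ifng on days 1 and 6. With captured sites in place of reads they were 1 and 0 for Pparg on days 1 and 2 and 42 in B cells, 0 for Lpin1 on day 6 and 6 in B cells, and 0 for Ifng on day 6 and 10 in B cells. With 100 kb left out around the bait, Lpin1 had 1 on day 6 and 1 in B cells. With 1-Mb windows, other-chromosome counts were 1 and 2 for Pparg on days 2 and 6, 2, 11 and 84 in B cells for Pparg, Lpin1 and Ifng, and 1 for each interaction. On other chromosomes in B cells, reads in place of captured sites gave 0 for Lpin1 and 268 for Ifng, at least 2 reads per captured site 13 and 7, and thinned to 1 depth 9 and 9. Against files numbered 1 only, Lpin1 had 0 windows on its own and 0 on other chromosomes; against files numbered 2 only, it had 0 and 2, Pparg 6 on its own, and Ifng 31 on other chromosomes. With the chromosome 10 regions left out, Ifng had 1 on day 1, and 256 of its own in B cells.

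Leaving out each library in turn, same-chromosome counts for Pparg ran from 0 to 3 on day 1, 0 to 1 on day 2, 0 to 4 on day 6 and 7 to 28 in B cells. For Lpin1 they ran from 0 to 4, 0 to 2, 0 to 111 and 1 to 5, and for Ifng from 0 to 1 on day 1 and 0 to 2 on day 6. On other chromosomes they ran from 0 to 2 in B cells for Pparg, 0 to 1 on day 2 and 0 to 9 in B cells for Lpin1, and 3 to 28 in B cells for Ifng. The left-out library leaves an arm of 1, assumed to vary like the others.

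The day 6 share of same-chromosome captured sites differed from day 0 by 5.26 percentage points for Pparg, 0.738 for Lpin1 and 6.16 for Ifng, and 4.05 over the 3 baits, where shares of reads were lower on day 6. With sizes of shifted correlations compared, Lpin1 and Ifng on days 1 and 2 (rho -0.105 and -0.124) and Pparg and Ifng on days 2 and 6 (-0.0765 and 0.00228) lost their call; with at least 2 reads per captured site, the last was 0.0194. Without 1 library it ran from -0.0114 to 0.0272. Of the named windows, 2 changed sign: with captured sites in place of reads, Pparg bait, B cells minus 3T3-L1, chromosome 6 window from 113.8 Mb (log2 difference -0.0503), and with reads, the day 2 window of Pparg from 79.5 Mb of chromosome 15 (0.13). Counting each window under each alternative, a call was lost 53 times and gained 11 times, and 68 and 8 times with a library left out.

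Gene-list tests and windows of list genes were not run, for want of an annotation of mm9. On simulated data the same-chromosome fits recovered 1% of 4-fold changes for Pparg, 0% for Lpin1 and 14% for Ifng. Every simulated window had the common biological coefficient of variation of its fit, 0.925, 1.19 and 0.426. These recovered shares therefore do not describe windows with a smaller spread.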

Other observations

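The tests of position in both lines and of site density were set beforehand, and the test of position in B cells alone was chosen only after the result was seen.

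Some chromosomes were captured by a bait more than others. The shares were not corrected for the copies of a chromosome in a cell line or for how well reads map to it. The Ifng bait captured chromosome 16 at 2.67 ± 0.378 (SD, n = 8) times the mean of other chromosomes in 3T3-L1 cells and 2.18 times in B cells, and chromosome 6 at 1.89 ± 0.262 (SD, n = 8) and 1.56 times. By reads per site, chromosome 16 stood at 3.16 ± 1.15 (SD, n = 8) times in 3T3-L1 cells and 1.66 in B cells. The B cell share of other-chromosome reads on it was 0.365 of that in 3T3-L1 files numbered 1 and 0.725 of that in files numbered 2. Chromosome 19 stood at 1.92 ± 0.0653 (SD, n = 8) for Lpin1, 1.58 ± 0.134 (SD, n = 8) for Pparg and 1.22 ± 0.0819 (SD, n = 8) for Ifng in 3T3-L1 cells. In B cells it stood at 2.03, 1.13 and 0.903. Chromosome X stood at 0.404, 0.431 and 0.446 times the mean for Pparg, Lpin1 and Ifng in 3T3-L1 cells and 0.345, 0.387 and 0.420 in B cells.

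Whether chromosomes dense in protein-coding genes were captured more was tested over 16 chromosomes in 6 relations, and none passed after adjustment. For Lpin1 in 3T3-L1 cells Pearson's r was 0.487 (permutation p = 0.0523, adjusted 0.147) and Spearman's rho 0.518 (permutation p = 0.0427, adjusted 0.198), with r 0.666 without chromosomes 7 and 11. For Pparg r was 0.457 (permutation p = 0.0733, adjusted 0.147) and rho 0.429 (permutation p = 0.0992, adjusted 0.198), with r 0.716 without those chromosomes. For Ifng r was -0.134 (permutation p = 0.664, adjusted 0.664) and rho 0.121 (permutation p = 0.658, adjusted 0.658), with r -0.0105 without them.

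A hypothesis is that regions at a like position along their chromosome meet the bait more often. It was set to need a rho of captured share with position above 0 for Ifng and Pparg and below 0 for Lpin1 in both lines, and 5 of the 6 rho met this with an interval without 0. In 3T3-L1 cells rho was 0.278 (interval 0.168 to 0.371) for Ifng, 0.204 (interval 0.119 to 0.287) for Pparg and 0.0512 (interval -0.00721 to 0.106) for Lpin1, so the hypothesis failed for Lpin1 there. In B cells rho was 0.427, 0.321 and -0.132 (interval -0.201 to -0.0698). A count for the explanation that regions at a like position meet the bait in B cells, 3 of 3 baits, was drawn from these values after they were seen, from 1 library per bait, and gives it no support. The density of HindIII sites is argued against as the whole cause, since Ifng and Lpin1 differed by 0.559 in B cells at the same sites.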
